A study of Mus musculus with 6 samples.

How the data were processed

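RNA-seq was done on marrow flushed from the femurs of wild-type and P2rx7 knockout mice aged 6 to 8 weeks, with 3 mice of each genotype and 1 library per mouse. Per the labels' protocols, RNA was purified with a Qiagen RNeasy Plus kit, and 1.3 µg of total RNA went into a library made with a SMARTer mRNA kit. The genome builds named in the submitters' processing notes are GRCm38 and mm10, which are names of the same mouse assembly. The aligner, the counter, the gene annotation and the use of strand in counting are not given in the sources used here.

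The authors deposited a table of 55291 genes and 18 columns that holds each gene's symbol, exon positions, strand and summed exon length, and then FPKM values and raw counts of the 6 libraries. Per the file headers, the columns of gene features have the layout of a featureCounts table. The deposited counts are whole numbers per gene symbol, with totals of 18716704 to 23575652 per library. The deposited FPKM values equal the count divided by gene length and by an effective library size, to a relative tolerance of 1e-06 in 100% of the values above 0 in each library. That effective size is the column total multiplied by a factor that matches a TMM factor over all genes, between 0.982 and 1.02. Gene symbols were not repeated, no row lacked a gene, and every per-sample column carried the name of a sample.

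Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and 16 alternative settings were fixed. A limma test on log2(FPKM + 1) had been planned for a file of FPKM alone, with edgeR in its place if raw counts were found. Counts were found, so edgeR was used and the limma test became an added alternative. Groups were taken from the genotype labels. The wild types are numbered and the knockouts are lettered, so the labels pair no samples, and the design holds 1 comparison.

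Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr, which left 15478. Libraries were scaled by TMM, and genotype was tested two-sided with glmQLFit and glmQLFTest. Benjamini-Hochberg adjusted p-values were taken over all tested genes, with a threshold of 0.05. Fold changes are log2 values of knockout over wild type with the standard error implied by the test. CPM values are TMM-scaled. The list scores are means of log2 CPM with a prior count of 2, less the mean of the wild types. P2rx7 was also tested with an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1. Ratios of genes with few counts carry an exact 95% binomial interval. A count of 0 allows up to 3 counts, which is 0.127 to 0.160 CPM per library. These intervals and floors, and the tests on counts of single groups of genes, cover counting error alone and take reads as independent, because the libraries carry no molecular identifiers described in the labels.

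Gene lists were tested with camera at a preset inter-gene correlation of 0.01, on lists with at least 5 tested members, and adjusted over the lists. Camera compares a list with all other genes. The correlation was also estimated per list as an alternative, and fry was run as a test of each list by itself. The 35 lists hold 695 entries, of which 682 are in the table and 583 passed the filter. They cover purinergic signalling, the inflammasome, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, mitochondrial dynamics, the TCA cycle with fatty acid oxidation, glycolysis, antioxidants, senescence, the cell cycle, interferon response, immediate early genes, heat shock with the unfolded protein response, ribosomal proteins, neighbours of P2rx7 and sex-linked genes. The cell type lists cover marrow stroma, osteoblasts, osteoclasts, adipocytes, chondrocytes, skeletal muscle, endothelium, erythroid cells, neutrophil precursors, mature neutrophils, monocytes and macrophages, dendritic cells, B cell precursors, mature B cells, plasma cells, T and NK cells, megakaryocytes, stem and progenitor cells, and eosinophils with basophils and mast cells.

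The rule for named genes took P2rx7 in every sample. It took the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 knockout values all lay on one side of the wild-type values, leaving out predicted genes, pseudogenes and variable segments of antigen receptors. Where fewer than 10 passed, up to 5 genes of smallest p were added as values that did not pass. From each list it took at most 4 members past the threshold, or else the 2 members of highest level. It also allowed all tested purinergic genes and took the 5 tested genes nearest to P2rx7. The values of 1 gene that the rule allowed are not reported here.

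The alternatives covered the pseudocount, the filter, the scaling, the variance model, each sample left out in turn, DESeq2 1.42.0 and the estimated correlation. A further 4 were added after the data were seen: the limma test on log2(FPKM + 1), robust edgeR, a fit of the 4 libraries that hold Gh transcripts, and a fit with that set of libraries as a term. In the last 2, the genotype effect rests on knockout A alone, which is assumed to vary like the other libraries. Camera was not run on the DESeq2 fit.

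The edgeR steps were tested on simulated counts for this comparison, with 200 of 15306 genes changed and 40 more, the members of 2 simulated lists, shifted 1.3-fold. At the adjusted threshold, 53.7% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 15 of 180 calls were false, while 154 were of the 200 genes and 11 of the 40 list members. Both shifted lists were called, as were 0 of 30 unchanged lists. The simulated genes were drawn independently of each other, whereas the estimated correlation was 0.84 in the real adipocyte list and 0.93 in the neutrophil precursor list. The 0 of 30 therefore does not show the error of the list test on correlated genes. Replicates were compared before averaging: the pair of libraries of a group that were closest had a chi-square of 4.43 per degree of freedom over genes, so no library repeated another within sampling noise. Positions are those of the deposited table and were not converted.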

Results

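Transcripts were counted in marrow flushed from mouse femurs, in 3 wild-type mice (WT 1, 2 and 3) and 3 P2rx7 knockout mice (knockouts A, B and C). P2rx7 encodes an ATP-gated cation channel, and the series title asks how ATP sensing through it bears on bone ageing and on the mitochondria of mesenchymal stromal cells. The libraries held totals of 20037343, 23575652 and 23311296 counts in WT 1, 2 and 3 and 22382281, 18716704 and 19663655 counts in knockouts A, B and C. Each library held counts for 23625 to 24371 of the 55291 genes. Correlations of log2 CPM across genes, which are not independent replicates, were 0.988 to 0.994 within a genotype and 0.977 to 0.992 between genotypes. The first principal component held 52.4% of the variance and ran from WT 2 at -40.8 to knockout B at 27.6, with WT 3 at -1.17 and knockout A at 7.80. The Y-linked genes Ddx3y and Eif2s3y were expressed in both genotypes, at 85.8 ± 3.87 and 47.4 ± 4.07 CPM in wild types and 90.5 ± 4.42 and 52.2 ± 6.08 CPM in knockouts (SD, n = 3). Xist had 3 to 8 counts per library.

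P2rx7 transcripts were lower in all 3 knockouts and were not lost. The gene lies on the plus strand of chromosome 5 at 122643911 to 122691432 (GRCm38), and its counts cover 5970 bases of exons. It had 1207, 1410 and 1453 counts in WT 1, 2 and 3 and 876, 722 and 748 in knockouts A, B and C. The level was 6.41 ± 0.195 FPKM in knockouts and 10.3 ± 0.232 FPKM in wild types (SD, n = 3). By the fold change of the edgeR fit, the knockout level was 62.8% of the wild-type level (95% interval 0.581 to 0.679 as a ratio). The log2 fold change was -0.67 ± 0.05 (SE), with an adjusted p of 0.0109 in edgeR's quasi-likelihood test. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The labels do not say which exons the knockout allele lacks, and counts over the whole gene do not show a deletion of part of it. Without knockout B the adjusted p was 0.0763 and without knockout C it was 0.0973, with the fold change at -0.67 and -0.65.

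Traces of other tissues divided the libraries into 2 sets, and these genes were chosen after their values were seen. Gh, which encodes growth hormone, had 54, 82, 75 and 23 counts in WT 1, 2, 3 and knockout A and 0 in knockouts B and C. Alb, which encodes serum albumin, had 46 and 36 counts in knockouts B and C and 0 in the other libraries. One set thus held all wild types and knockout A, and the other held only knockouts, so that the second set alone gives no comparison. The division was not complete for every gene: Pomc, also expressed in the pituitary, had 29, 28, 41 and 18 counts in WT 1, 2, 3 and knockout A and 8 and 1 in knockouts B and C. Whether the fit used only the first set or had the set as a term, its genotype effect rested on knockout A alone against 3 wild types. Among the 4 libraries of the first set the log2 fold change of P2rx7 was -0.64 (adjusted p = 0.516, edgeR), and with the set as a term in the fit of all 6 libraries it was -0.64 (adjusted p = 0.112).

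The 5 tested genes nearest to P2rx7 did not pass the threshold. P2rx4, another ATP-gated channel that starts 16.1 kb beyond P2rx7, was at 172 ± 11.7 CPM in knockouts and 147 ± 6.52 CPM in wild types (SD, n = 3; adjusted p = 0.178, edgeR). Log2 fold changes were -0.07 for Ift81, 0.08 for Camkk2, -0.00 for Anapc5 and -0.18 for Atp2a2, the pump that returns calcium to the endoplasmic reticulum. The list of P2rx7 neighbours was not shifted by camera (28 tested, adjusted p = 0.267), with 3 higher and 1 lower when adjusted over the list alone and 0 over all genes tested. Of the 18 tested purinergic genes, 0 passed over all genes tested and 0 when adjusted over the list alone, and the list was not shifted (adjusted p = 0.226). The UDP receptor P2ry6 was at 263 ± 23.6 CPM in knockouts and 274 ± 15.8 CPM in wild types, and the ectonucleotidase Entpd1 was at 166 ± 1.95 and 168 ± 7.27 CPM (SD, n = 3). Nt5e, the enzyme that makes adenosine from AMP, was at 4.43 ± 0.287 CPM in knockouts and 3.05 ± 0.508 CPM in wild types (adjusted p = 0.192, edgeR).

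Across the transcriptome, genes of antibody chains rose most in the knockouts, and a small group of genes that includes macrophage receptors fell. Igha, the constant region of IgA, rose from 8.52 ± 5.09 CPM in wild types to 98.3 ± 5.33 CPM in knockouts (SD, n = 3), a log2 fold change of 3.51 ± 0.32 (SE, adjusted p = 0.0142, edgeR). Jchain, which joins IgA and IgM into polymers, rose by 3.75 ± 0.34 on the log2 scale (adjusted p = 0.0142). The light chain constant regions Igkc and Iglc1 rose by 3.40 ± 0.36 and 4.06 ± 0.46. Wild-type levels differed between mice: without WT 3 the log2 fold changes of Igha, Jchain and Igkc were 4.11, 4.40 and 4.17, and without WT 2 that of Iglv1 was 5.38. Variable segments lie outside the rule for named genes, and 3 of them also rose. These were Iglv1 by 4.38 on the log2 scale, Igkv10-96 from 2 counts in all wild types to 82 in all knockouts, and Ighv1-81 from 2 to 120. The ratio for Igkv10-96 was 44.7 (exact 95% binomial interval 11.98 to 375) and that for Ighv1-81 was 65.4 (17.7 to 546). Both wild-type counts of Ighv1-81 were in WT 3, so without that library this gene has no fold change, only counts against 0. Reads of antibody segments can be split between near-identical copies, so single segments are uncertain.

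Besides antibody genes, 2 genes rose. Atp6v0d2, a subunit of the proton pump that is abundant in osteoclasts, rose from 18.4 ± 1.63 to 38.3 ± 5.69 CPM (log2 fold change 1.06 ± 0.12 SE, adjusted p = 0.0318, edgeR). Ifi27l2a, an interferon-induced gene, rose from 61.6 ± 3.97 to 93.4 ± 8.17 CPM (0.60 ± 0.08, adjusted p = 0.0490). The next genes by p did not pass. Their log2 fold changes were 1.73 for the signalling ligand Wnt4, 3.76 for the IgG2b constant region Ighg2b, 0.94 for the folate receptor Folr2, 0.33 for the interferon-inducible Rtp4 and 0.43 for the class I gene H2-T23. Their adjusted p-values were 0.0575 to 0.0665. Rtp4 shares its span with Masp1 on the other strand. Whether their exons overlap was not examined. Reads in any shared exon cannot be told apart without known strand, so the value of Rtp4 is less certain. The span of Folr2 holds 2 genes on the other strand, with at most 39 counts in a library against at least 102 of Folr2.

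The genes that fell besides P2rx7 were 6. Vsig4, a complement receptor of tissue macrophages, fell from 6.35 ± 0.962 to 1.60 ± 0.102 CPM (SD, n = 3), a log2 fold change of -1.98 ± 0.17 (SE, adjusted p = 0.0142, edgeR). Cd163, the macrophage scavenger receptor for haemoglobin bound to haptoglobin, fell from 72.4 ± 6.40 to 43.3 ± 4.36 CPM (-0.74 ± 0.09, adjusted p = 0.0486). Gata6, a transcription factor of heart and gut development and of peritoneal macrophages, fell from 4.43 ± 0.338 to 1.91 ± 0.152 CPM (-1.21 ± 0.15, adjusted p = 0.0490). The potassium channel gene Kcnj10 fell by 2.04 on the log2 scale and the amino acid transporter gene Slc38a4 by 2.19. Paqr9, a receptor of the progestin and adipoQ receptor family, had 61 counts in all wild types and 5 in all knockouts, a ratio of 0.0893 (exact 95% binomial interval 0.0280 to 0.220). The next genes by p did not pass. The log2 fold changes were -0.99 for Col2a1, the type II collagen of cartilage, -0.57 for Tshz3, -2.27 for the integrin gene Itgad, -1.65 for Dcaf12l1 and -2.94 for Stmn2, at adjusted p-values of 0.0619 to 0.0776. Stmn2 had 22, 32 and 32 counts in WT 1, 2 and 3 and 7, 1 and 2 in knockouts A, B and C. As for Gh and Pomc, knockout A lay between the wild types and knockouts B and C. For Stmn2 the set of libraries and the genotype cannot be told apart. The span of Itgad holds 5 other genes, 4 of them on the other strand, with up to 49 counts in a library against 3 in the lowest library of Itgad, so its value is less certain. That of Tshz3 also holds 5, with at most 34 counts against at least 280.

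**Figure D1:**
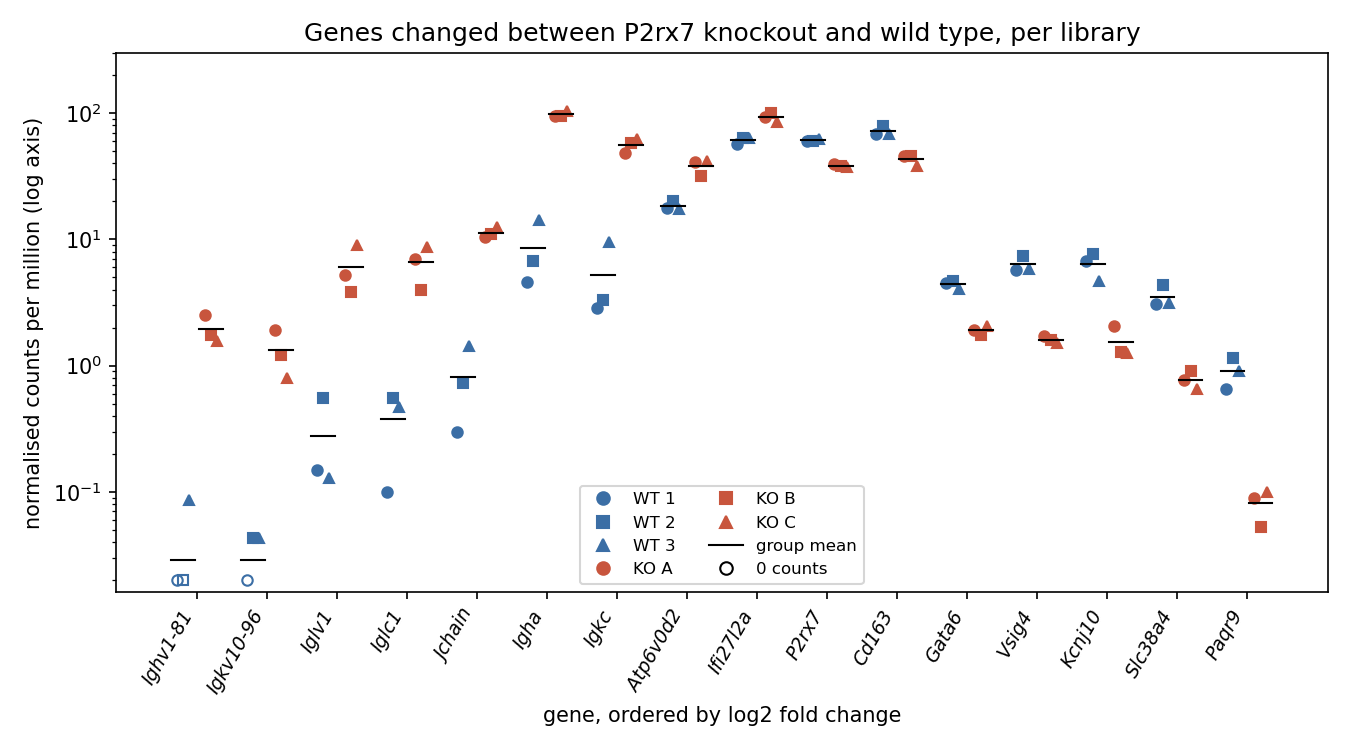
CPM on a log axis of the 16 genes past the threshold, ordered by log2 fold change, with 1 point per library (blue for wild type, red for P2rx7 knockout), black lines for group means and open symbols at the lower edge for libraries with 0 counts. In each gene the 3 knockouts lie on one side of the 3 wild types; P2rx7 remains at 38.4 CPM in knockouts against 61.2 CPM in wild types.

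In all, 16 of 15478 tested genes changed at an adjusted p below 0.05 (edgeR), 9 higher and 7 lower in knockouts, and 13 of them by at least 2-fold. An unadjusted p below 0.05 was reached by 2564 genes, where 774 would be expected by chance. The genotypes did not overlap in 21.9% of genes, where chance gives 10%. Genes are not independent, and this excess does not tell genotype from the 2 sets of libraries. Little of the excess in p-values was left in the fits given below that handle the sets, which rest on knockout A alone. The count of changed genes depended on single libraries. It was 5 without WT 1, 45 without WT 2, 172 without WT 3, 8 without knockout A, and 0 without knockout B or C. In these last fits 1468 and 1772 genes had an unadjusted p below 0.05. It was 0 among the 4 libraries of the first set and 0 with the set as a term (668 and 894 genes at an unadjusted p below 0.05). With the set as a term, where knockout A alone carries the effect, each of the 16 genes kept its direction. The log2 fold changes were then 3.47 for Igha, 3.63 for Jchain, 3.18 for Igkc and 1.16 for Atp6v0d2. They were -1.89 for Vsig4, -1.62 for Kcnj10, -2.20 for Slc38a4 and -3.26 for Paqr9. The 16 genes had been called with knockout A included, and in each of them knockout A lay beyond all wild types. That the direction held was therefore fixed by the choice of genes, and these sizes are no separate support for the calls. On all libraries DESeq2 called 496 genes and edgeR on all genes with a count called 970.

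Of the 33 gene lists that could be tested, 17 shifted relative to all other genes by camera, 11 upwards and 6 downwards. With an estimated correlation the plasma cell list alone held (adjusted p = 0.0240). The adjusted p of the other 16 lists was 0.477 to 0.557 with an estimated correlation. Fry, which tests each list by itself for a shift in 1 direction, also called only 1 list, the plasma cell list (adjusted p = 0.00965, fry). The next lowest adjusted p by fry was 0.146, for the interferon and osteoclast lists. The mixed version of fry, which allows members to move in either direction, called 13 lists. The 33 tested lists share genes and mice and are not independent. The scores of 12 of them did not overlap between genotypes, where chance gives 10% for each list. Of the 17 shifted lists, the scores of 8 did not overlap, 5 of them higher and 3 lower in knockouts.

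The plasma cell list shifted upwards most (adjusted p = 2.09e-21), with 3 of its 9 tested members higher over all genes tested and 5 when adjusted over the list alone. The 3 that passed over all genes tested were the antibody chain genes Igha and Iglv1 and Jchain. Ighg2b, also of this list, had a log2 fold change of 3.76 and did not pass over all genes tested. Other members, chosen after their values were seen, were Sdc1 at 170 ± 8.97 CPM in knockouts and 160 ± 18.2 CPM in wild types and Xbp1, a transcription factor of secretory cells, at 202 ± 8.22 and 195 ± 10.2 CPM (SD, n = 3). Counts of the plasma cell genes Mzb1 and Tnfrsf17 were at most 2 in any library. The mature B cell list shifted upwards (adjusted p = 0.000269), with 0 of 6 members passing over all genes tested and 3 higher when adjusted over the list alone. Its adjusted p was 0.492 with an estimated correlation. The list includes the antibody genes Ighd and Ighm, so it is not separate from the antibody rise. Without antibody genes its score was 0.46 ± 0.27 (SE) higher in knockouts on the log2 scale, and camera was not run on that reduced list. The median FPKM of the list was 0.114 to 0.452 across libraries. Of that list, Cd37, far above this median, was at 83.1 ± 4.45 CPM in knockouts and 63.5 ± 4.26 CPM in wild types. The B cell precursor list was not shifted (adjusted p = 0.647), with 1 of 7 members lower when adjusted over the list alone. Its most abundant members here were Akap12 at 368 ± 25.2 against 501 ± 35.8 CPM and Ebf1 at 169 ± 7.35 against 143 ± 25.3 CPM, both also expressed outside the B lineage.

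Interferon-response genes shifted upwards (adjusted p = 1.30e-18), with Ifi27l2a past the threshold over all genes tested and 18 of 26 members higher when adjusted over the list alone. The adjusted p was 0.477 with an estimated correlation. The inflammasome list also shifted upwards (adjusted p = 0.0042, and 0.532 with an estimated correlation), with 0 of 18 members past the threshold and 1 higher when adjusted over the list alone. Il1rn, the antagonist of the interleukin-1 receptor, was at 870 ± 96.5 CPM in knockouts and 588 ± 172 CPM in wild types (SD, n = 3; adjusted p = 0.232, edgeR). With the set of libraries as a term the median log2 fold change of the inflammasome list stayed at 0.12, against 0.11 on all libraries, while its adjusted p was 0.124.

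Lists of stromal and bone cells shifted upwards in part. The adipocyte list had a median log2 fold change of 0.65 and positive values in 14 of 14 members (adjusted p = 1.49e-12), with 9 higher when adjusted over the list alone. The adjusted p was 0.492 with an estimated correlation. Part of the size rested on WT 2, whose score was -0.82 against 0.47 and 0.35 in WT 1 and 3; without WT 2 the median of the adipocyte list was 0.48 and that of the marrow stromal list 0.23, and both were still shifted. The fatty acid transporter Cd36 was at 442 ± 22.6 CPM in knockouts and 322 ± 27.9 CPM in wild types. The marrow stromal list had a median of 0.36 (adjusted p = 2.31e-05), with 6 of 22 members higher and 2 lower when adjusted over the list alone. The adjusted p was 0.532 with an estimated correlation. Its most abundant member, the chemokine Cxcl12, was at 4540 ± 460 CPM in knockouts and 2397 ± 956 CPM in wild types (SD, n = 3; adjusted p = 0.192, edgeR). The osteoclast list shifted upwards (adjusted p = 0.00186, and 0.477 with an estimated correlation), with Atp6v0d2 past the threshold and 2 of 13 members higher when adjusted over the list alone. The osteoblast list was not shifted (adjusted p = 0.113) but passed without WT 3 (median 0.24, adjusted p = 0.00818) and with the set of libraries as a term (0.24, adjusted p = 0.0297), against a median of 0.22 on all libraries. Its most abundant members Col1a1 and Col1a2, the chains of type I collagen, were at 8140 ± 371 and 6535 ± 319 CPM in knockouts and 9756 ± 1088 and 6972 ± 747 CPM in wild types. Neither the chondrocyte list (median -0.00, adjusted p = 0.226; 0.04 and 0.0237 without WT 3) nor the skeletal muscle list (adjusted p = 0.557) was shifted. Col2a1 and Comp, a cartilage matrix protein, had log2 fold changes of opposite sign, -0.99 and 1.18, and Acta1 and Actn3 had -0.67 and 0.10. When adjusted over the list alone, 1 member was higher and 1 lower in the chondrocyte list, and 0 passed in the osteoblast and skeletal muscle lists.

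The lists of neutrophil precursors, megakaryocytes, T and NK cells and stem and progenitor cells shifted upwards. In each of them the score of WT 3 lay above that of knockout A. This was also so in the mature B cell list (WT 3 at 0.53, knockout A at 0.28) and in the inflammasome list (0.087 and 0.043). The neutrophil precursor list had a median log2 fold change of 1.41 (adjusted p = 0.0042, and 0.557 with an estimated correlation), but its score in knockout A was -0.40 on the log2 scale relative to the wild-type mean, inside the wild-type range of -1.19 to 1.17, against 2.05 and 1.68 in knockouts B and C. Its call ended without WT 2 (median 0.90, adjusted p = 0.0701) and without knockout B (0.93, adjusted p = 0.0899). Mpo, the peroxidase of neutrophil granules, was at 183 ± 119 CPM in knockouts and 55.6 ± 52.5 CPM in wild types. The megakaryocyte list had a median of 0.88 (adjusted p = 0.000315, and 0.557 with an estimated correlation), the T and NK cell list 1.31 (adjusted p = 0.0243, and 0.532 with an estimated correlation) and the stem and progenitor list 0.42 (adjusted p = 0.0350, and 0.557 with an estimated correlation). The T and NK cell list was near the floor, with a median of 0.0234 to 0.474 FPKM across libraries. Only 7 of its 18 members were tested, 5 with a positive and 2 with a negative log2 fold change. The negative ones were Cd28 and Cd4. When adjusted over the list alone, 0 members of the neutrophil precursor, megakaryocyte and stem and progenitor lists passed, as did 3 higher and 1 lower of the T and NK cell list. The call of the stem and progenitor list ended without WT 1 (median 0.24, adjusted p = 0.284), without knockout B (0.22, adjusted p = 0.133) and without knockout C (0.28, adjusted p = 0.0858). With the set of libraries as a term the median of the neutrophil precursor list was -0.27, that of the stem and progenitor list -0.20 and that of the megakaryocyte list -0.06. None of these 3 lists or the T and NK cell list (0.42) was then shifted. Pf4, a platelet chemokine, was at 181 ± 12.01 CPM in knockouts and 202 ± 37.8 CPM in wild types, Cd28 at 21.5 ± 0.935 and 29.4 ± 4.35 CPM, and Ly6a at 97.1 ± 14.6 and 119 ± 25.3 CPM.

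**Figure D2:**
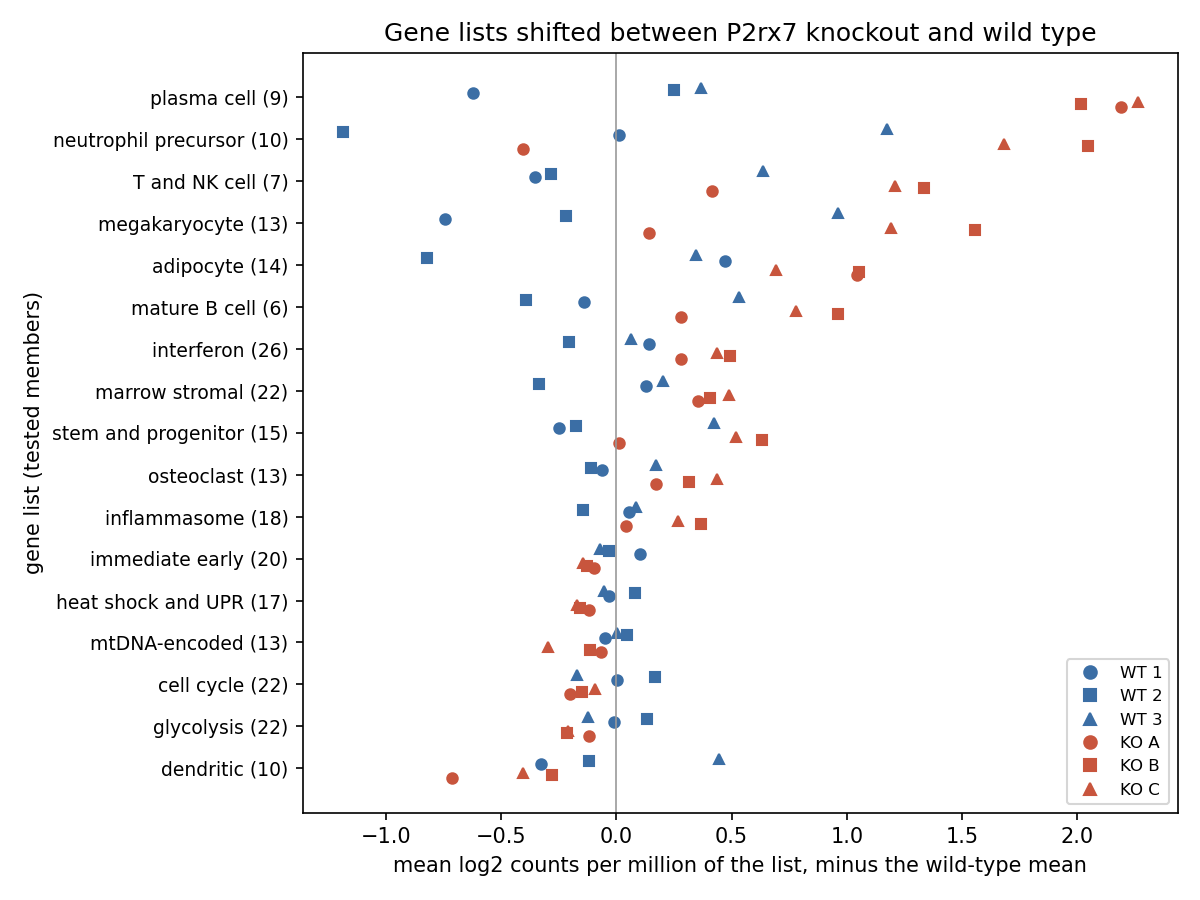
Mean log2 CPM of each of the 17 shifted gene lists in each library, minus the mean of the wild types, with the number of tested members in parentheses (blue for wild type, red for P2rx7 knockout). The plasma cell list separates the genotypes furthest, and in the neutrophil precursor list knockout A at -0.40 lies among the wild types.

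The lists that shifted downwards did so by small amounts. Glycolysis genes had a median log2 fold change of -0.22, with 18 of 22 members negative (adjusted p = 2.31e-05, and 0.532 with an estimated correlation). Aldoa and Pkm, enzymes of that pathway, were at 867 ± 19.4 and 756 ± 45.6 CPM in knockouts and 955 ± 67.6 and 903 ± 97.6 CPM in wild types (SD, n = 3). Cell cycle genes had a median of -0.19 (adjusted p = 0.000314, and 0.557 with an estimated correlation), and the proliferation marker Mki67 was at 146 ± 6.76 and 178 ± 21.0 CPM. Heat shock and unfolded protein response genes had a median of -0.16 (adjusted p = 0.000314, and 0.492 with an estimated correlation) and immediate early genes one of -0.13 (adjusted p = 0.00174, and 0.532 with an estimated correlation). The chaperone gene Hspa5 was at 828 ± 33.8 and 958 ± 116 CPM, and the transcription factor Egr1 at 270 ± 9.46 and 303 ± 8.45 CPM. The dendritic cell list had a median of -0.30 (adjusted p = 0.00583, and 0.532 with an estimated correlation). Its call ended without WT 3, where the median was 0.07 (adjusted p = 0.490), and without knockout A (-0.20, adjusted p = 0.105); that of the immediate early list ended without WT 1, where the median was -0.05 (adjusted p = 0.124). When adjusted over the list alone, 0 members passed in the glycolysis and cell cycle lists, 1 was lower in the heat shock list, 2 were lower in the immediate early list, and 4 were lower and 1 higher in the dendritic cell list.

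Mitochondrial genes, which the series title concerns, had small fold changes. The 13 mitochondrially encoded genes had a median log2 fold change of -0.10 with 12 negative (adjusted p = 0.0042, and 0.557 with an estimated correlation), and 0 passed when adjusted over the list alone. The call of the list ended without knockout C (median -0.06, adjusted p = 0.0778) and with the set of libraries as a term (median -0.06, adjusted p = 0.134). mt-Co1, a subunit of cytochrome c oxidase, was at 6513 ± 109 CPM in knockouts and 6828 ± 44.9 CPM in wild types. Nuclear-encoded oxidative phosphorylation genes were not shifted (45 tested, median 0.03, adjusted p = 0.104). They passed as shifted upwards without knockout A (median 0.07, adjusted p = 0.0112) and in limma on log2(FPKM + 1) (median 0.03, adjusted p = 0.0257). The ATP synthase subunit gene Atp5b was at 657 ± 19.0 and 667 ± 22.9 CPM. Mitochondrial dynamics (adjusted p = 0.556), the TCA cycle with fatty acid oxidation (0.176), antioxidants (0.571) and senescence (median -0.13, 0.147) were not shifted either, but the senescence list passed without WT 3 (-0.15, adjusted p = 0.0210). Citrate synthase, Cs, was at 246 ± 7.56 and 256 ± 15.4 CPM and the mitochondrial carrier gene Ucp2 at 656 ± 58.5 and 652 ± 17.5 CPM. Catalase, Cat, was at 864 ± 53.6 and 832 ± 81.6 CPM. When adjusted over the list alone, 0 members passed in the oxidative phosphorylation, dynamics and TCA lists, 1 was lower among antioxidants and 1 was higher among senescence genes. Ribosomal protein genes had a median of -0.04 and were not shifted (adjusted p = 0.0935), but passed as shifted downwards without knockout B (median -0.04, adjusted p = 0.0302), without knockout C (median -0.06, adjusted p = 0.00280) and in limma on log2(FPKM + 1) (-0.04, adjusted p = 0.0267). Their median was -0.13 with the set of libraries as a term (adjusted p = 1.42e-07) and -0.13 among the 4 libraries of the first set (adjusted p = 5.91e-07), fits in which the effect is that of knockout A alone. In the list, Rpl4 was at 863 ± 49.9 and 913 ± 26.0 CPM, and 0 of its 31 members passed when adjusted over the list alone.

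Transcripts of stromal cells and macrophages were abundant in all 6 libraries, and transcripts of red cells were nearly undetected. All values here are of libraries with this makeup, which limits how far they stand for whole marrow. The genes of highest mean level included Apoe at 4551 ± 386 FPKM, the macrophage lysozyme Lyz2 at 4190 ± 319 FPKM, C1qb at 1849 ± 121 FPKM and the smooth muscle actin Acta2 at 1702 ± 394 FPKM (SD over all libraries, n = 6), named for their level after the values were seen. The median FPKM of the marrow stromal list was 22.2 ± 0.443 in knockouts and 19.2 ± 2.09 in wild types. That of the monocyte and macrophage list was 33.4 ± 3.56 in knockouts and 59.1 ± 15.5 in wild types, with each knockout below each wild type. Yet 12 of its 19 members had a positive log2 fold change, and its list scores overlapped between genotypes. The lower median FPKM therefore does not show a fall of the list as a whole. The 4 globin genes together had 0 to 10 counts per library, and the median FPKM of the erythroid list was at most 0.0829 in any library. Only 2 erythroid genes passed the filter, Tfrc and Gata1, too few for a list test. Both were higher when adjusted over these 2 genes alone but not over all genes tested. Gata1 overlapped between genotypes, with 0.764 CPM in knockout A and 1.04 CPM in WT 3. Tfrc, at 126 ± 5.53 CPM in knockouts and 108 ± 1.88 CPM in wild types, stood far above the median of the list. The values of these 2 genes do not show a rise of erythroid cells. The monocyte and macrophage list was not shifted (adjusted p = 0.945; median 0.13, mean -0.05, and a test that pointed downwards), with Cd163 past the threshold and 3 of 19 members lower when adjusted over the list alone. The mature neutrophil list (median -0.40, adjusted p = 0.0628), the endothelial list (0.21, adjusted p = 0.226) and the list of eosinophils, basophils and mast cells (-0.41, adjusted p = 0.342) were not shifted. The mature neutrophil list passed without WT 2 (median -0.70, adjusted p = 4.92e-07), without knockout B (-0.61, adjusted p = 0.000416) and without knockout C (-0.76, adjusted p = 0.000419). The endothelial list passed without WT 3 (0.54, adjusted p = 0.00188) and without knockout A (0.45, adjusted p = 0.00438), and the list of eosinophils, basophils and mast cells without knockout B (-0.77, adjusted p = 0.0107). In knockout A, which alone carries the genotype effect once the set of libraries is a term, the medians of these 3 lists were -2.16, -0.43 and -0.84, and all 3 passed (adjusted p = 1.57e-18, 0.0196 and 0.00283), the endothelial list with a median of the opposite sign to that without WT 3 or knockout A. Ngp, a granule protein of maturing neutrophils, was at 49.8 ± 32.3 and 85.7 ± 42.7 CPM, the endothelial cadherin Cdh5 at 46.1 ± 15.2 and 39.6 ± 19.0 CPM, and the eosinophil receptor Ccr3 at 5.10 ± 1.44 and 9.38 ± 1.89 CPM, in knockouts and wild types. When adjusted over the list alone, 0 members passed in the mature neutrophil and endothelial lists and 1 was lower in the last.

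**Figure D3:**
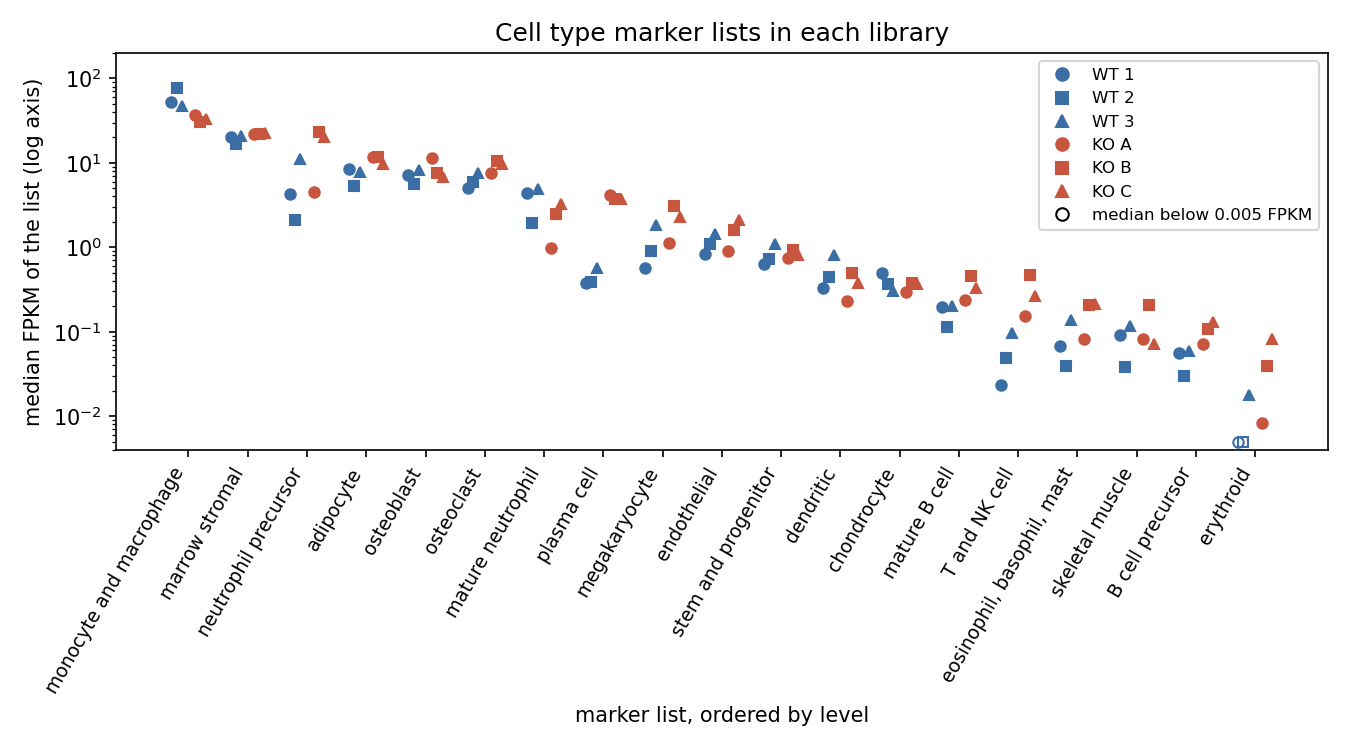
Median FPKM, on a log axis, of each of the 19 cell type marker lists in each library (blue for wild type, red for P2rx7 knockout), with open symbols at the lower edge for medians below 0.005 FPKM. By the mean of each genotype the monocyte and macrophage list and the marrow stromal list lie highest and the erythroid list lowest, at no more than 0.0829 FPKM in any library.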

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

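No paired analysis was possible because the wild types are numbered and the knockouts are lettered. The settings that used the set of libraries, robust edgeR and limma on log2(FPKM + 1) were chosen after seeing the data. P2rx7 was lower in knockouts under all 19 settings run for it, at -0.42 with a pseudocount of 5, which shrinks fold changes. Its log2 fold change was -0.69 to -0.65 when a library was left out, where its call ended without knockout B or C, and -0.64 without a call both among the 4 libraries with Gh transcripts and with the set of libraries as a term. These fits hold fewer samples or estimate 1 more term. Among the 15 other called genes no direction reversed; each kept its call in 5 to 14 of the 12 to 19 settings that tested it. DESeq2, whose fit was not used for lists, kept all 16 genes and called 496 (236 higher, 260 lower), and edgeR on all genes with a count kept all 16 and called 970 (518 higher, 452 lower). The count was 5 with edgeR on the 7632 genes that passed a filter of FPKM 5. With limma tests on FPKM, in which 12481 genes passed the filter of FPKM 1, it was 2 and 6 with pseudocounts of 0.1 and 5, 5 with quantile normalization, 8 without the trend and 4 with robust hyperparameters. It was 0 to 172 when a library was left out, 0 among the 4 libraries with Gh transcripts and 0 with the set of libraries as a term, against 16 with median-ratio scaling, 13 with robust edgeR and 11 with limma on log2(FPKM + 1). Beyond smaller sets of samples or genes, the cause was not tested. The median log2 fold change over shared genes moved by -0.00751 to 0.00489.

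The count of shifted lists was 12 to 20 in all settings but the estimated correlation, where it was 1. Of the 17 lists, 9 kept their call in all other settings that tested them (the plasma cell and mature B cell lists were tested in 18 of the 19), and 8 lists that were not shifted passed in at least 1 setting: ribosomal in 10, nuclear oxidative phosphorylation in 8, mature neutrophil in 6, eosinophil, basophil and mast cell in 3, osteoblast and endothelial in 2 each (the latter also reversed in 2), and chondrocyte and senescence in 1 each. The stem and progenitor list lost its call in 11 settings and the dendritic list in 9. The lists that reversed did so among the 4 libraries with Gh transcripts and with the set of libraries as a term: the endothelial list to -0.43 and -0.43, the neutrophil precursor list to -0.27 and -0.27 and the stem and progenitor list to -0.21 and -0.20; a cause beyond the smaller contrast of knockout A alone was not tested. In simulated counts of this depth 53.7% of 1.5-fold changes were called, as were 11 of 40 genes shifted 1.3-fold. The simulated libraries of a group differed by depth and independent noise alone, so real changes of these sizes may be called less often.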

Other observations

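All gene groups and tests in this part were chosen after the data were seen. Of 13 genes of antigen presentation on MHC class I, picked by their values and not tested as a group, 13 had a positive log2 fold change, with a median of 0.43; edgeR called 0 of them and DESeq2 11. H2-K1 was at 860 ± 37.3 CPM in knockouts and 623 ± 74.4 CPM in wild types, B2m at 2958 ± 142 and 2322 ± 220 CPM and the transactivator Nlrc5 at 80.5 ± 8.64 and 56.5 ± 4.66 CPM (SD, n = 3), with edgeR adjusted p-values of 0.125, 0.161 and 0.101. Of 15 contractile genes, also chosen after the data were seen and not tested as a group, 15 had a negative log2 fold change. Their median was -0.44, and edgeR called 0 of them and DESeq2 6. Acta2, 1 of these genes, was at 3168 ± 437 CPM in knockouts and 4312 ± 795 CPM in wild types, with overlap between the genotypes.

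The first pattern was the antibody transcripts. Antibody genes together were at 272 ± 36.1 CPM in knockouts and 31.3 ± 21.0 CPM in wild types (SD, n = 3), 8.71-fold higher, or 14.2-fold without WT 3, which had 55.4 CPM against 17.9 and 20.4 CPM in WT 1 and 2. Reads from 1 foreign library shared by the knockouts would keep these genes in 1 ratio, but the chi-square was 13.3 per degree of freedom, a test that takes reads as independent, against 0.901 to 3.90 in 99 sets of other genes of like counts in the same libraries: Ighg1 had 97, 73 and 303 counts and Ighg3 29, 111 and 11 in knockouts A, B and C. More blood cells of every type would raise other lists alike. The scores of 9 of 9 lists lay below that of the antibody genes by more than 2 standard errors of the difference. These were the mature neutrophil, neutrophil precursor, dendritic, eosinophil, B precursor, mature B without antibody genes, T and NK, megakaryocyte and stem cell lists. The antibody score covered 22 of 393 antibody genes. Tested antibody genes such as Ighv1-81, with 2 counts in wild types and 120 in knockouts, passed the filter through the knockouts. That choice favours a high antibody score, and 2 standard errors is a loose cut with 3 mice against 3. Macrophages, abundant in every library, were left out because they would hide a small share. The same limit holds for abundant listed genes that are also expressed outside the listed cell type, such as Akap12 and Ebf1. In the neutrophil precursor list the difference was 2.25 on the log2 scale with a standard error of 0.920, from 3 mice against 3. More blood cells in the knockout libraries are therefore not excluded. Plasma cells may be the source, and this stays open. The plasma cell genes Mzb1 and Tnfrsf17, of low level in all libraries here, had 6 counts in knockouts and 2 in wild types (exact binomial p = 0.164). Jchain had 687 counts in knockouts. The counts of Mzb1 and Tnfrsf17 are too few to decide, and a difference between the genotypes themselves stays open as well.

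The second pattern was the traces of other tissues, whose 2 sets of libraries overlap with genotype. The ratio of 5 pituitary genes (Gh, Prl, Pcsk1n, Pomc and Cga) did not differ detectably over the 4 libraries that held Gh (Fisher's exact test by resampling, p = 0.636, 665 counts), as 1 source would give, with reads taken as independent; the 9 counts of these genes in knockouts B and C were all of Pomc. Alb and Myh6, genes of liver and heart, stood in a ratio that did not differ detectably between knockouts B and C (Fisher's exact test, p = 0.0962, 176 counts), and libraries handled in 2 groups, which the labels do not record, are a candidate explanation. Whether the sets, rather than genotype, made the calls could be asked in part in knockout A, which shares its set with the wild types. Without knockout A 8 genes were called, and 5 remained once trace genes were left out. Trace genes mark the sets, so leaving them out removes calls that follow the sets, and the shares cover only the other calls. In the 5 genes the log2 fold change of knockout A had a median of 93.2% of that in knockouts B and C. P2rx7, the targeted gene, was at 92.6%, Jchain at 95.4%, Igha at 98.3%, Vsig4 at 93.2% and Smpd3 at 21.7%. Jchain and Igha both belong to the antibody pattern. A single library cannot decide whether the sets made the calls, and both shares use the same wild types. For genes such as Smpd3 the set and the genotype cannot be told apart.

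Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split called 16 genes, and 2 of the 10 splits, itself included, called as many; the highest other count was 36, from WT 1, WT 2 and knockout A against WT 3 and knockouts B and C. For gene lists 1 split, the real one, shifted 17, and the highest other count was 16. The split with 36 genes points to a structure of the samples that cuts across genotype: it held endothelial genes such as Pecam1 (357, 496 and 409 counts in WT 1, WT 2 and knockout A; 973, 704 and 842 in WT 3 and knockouts B and C) and Elane of neutrophil precursors (131, 58 and 136; 576, 1011 and 703).

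The third pattern was the near absence of red cell transcripts from flushed marrow. Removal of globin transcripts alone would leave other erythroid genes, but their highest median in any library was 0.0334 FPKM. Removal of red cells alone would leave B cell precursors, but the highest median of the B precursor list in any library was 0.130 FPKM. Few red cell and B precursor transcripts beside abundant Col1a1, Acta2, Apoe and Lyz2 may mean that the libraries do not stand for whole fresh marrow, and whether the cells were cultured, sorted or otherwise enriched stays open, was not tested and is not mentioned in the labels. Late neutrophil genes still had 879 to 7135 counts per library, and no biological explanation was tested, because the pattern is shared by both genotypes.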
